A study of Drosophila melanogaster with 6 samples.

How the data were processed

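Messenger RNA was sequenced from heads of adult Drosophila melanogaster of 2 genotypes, 3 samples each: flies mutant for the microRNA gene mir-210, and w1118, the white-eyed laboratory strain used as control. Per the labels, RNA was extracted with Trizol and libraries were sequenced on an Illumina platform. FastQC, HISAT2, featureCounts and DESeq, with genome build dm6, are named in the submitters' processing notes, without roles, order or versions. Strandedness, read trimming and any filter on genes are not given in the sources used here, so reads of overlapping genes on opposite strands may not be separable.

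The data analysed were the authors' deposited table of 1 comparison, with 13541 genes. For each group the table gives a mean signal, the average over the group's libraries of read counts divided by a size factor, by the authors. It also holds a log2 fold change, mutant over control, fitted by the authors, and the authors' p-value and adjusted p-value, per the file headers. Gene coordinates, lengths and biotypes come from the same deposited table. Adjusted values matched a Benjamini-Hochberg adjustment over 11155 genes to within 3.8e-15; the other 2386 genes are listed with an adjusted value of 1 and were treated as not tested. Of these, 23 have no p-value. Where both means exceeded 5 (10087 genes), the log2 ratio of the means differed from the deposited log2 fold change by at most 0.07.

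A count-based test had been planned for counts per sample. As the table holds group means and the authors' own p-values, the main results are the authors' calls, at an adjusted p under 0.05, and no test of these calls was added to them. The table has no columns for single samples.

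Values of single libraries were recovered from the group means as follows. Each mean is a sum of 3 whole read counts, each multiplied by a step that belongs to 1 library. Low means gave the 3 steps of each group. Every mean of at most 10000 was then searched for whole-number combinations of the 3 steps. Exactly 1 combination was found for 13193 of 13193 mutant means and 13225 of 13225 control means, within 2.8e-11 of a read, and 13169 genes (97.3%) were recovered in all 6 libraries. The other 372 genes, with a mean over 10000 in either group, were not searched. The recovered genes hold 37.3% of the summed mutant means and 42.2% of the summed control means. Size factors computed from the recovered reads by the median of ratios differed from those given by the steps by at most 1.05%. In means made from simulated reads of genes with means under 3000 (5056 mutant and 5546 control), and in simulated means from 3000 to 10000 (257 and 252), 100% were recovered exactly. Recovered libraries carry no replicate number, and are named deepest, middle and shallowest within their group by size factor. In the mutant the size factors were 0.973, 0.826 and 0.672, and in the control 1.72, 1.08 and 1.00. Reads in recovered genes ranged from 6257409 to 16462836 per library.

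limma 3.58.1 in R 4.3.3 (trend and robust options) was run on log2(normalized count + 1) of the recovered libraries for genes with a mean of at least 1. This was an alternative added after the file was seen. On that scale the fold change of low genes is understated. On simulated reads of 11596 genes with 200 changed, mutant against control, it recovered 66% of 2-fold and 100% of 4-fold changes, with 3.49% false calls. With the measured difference between the deepest and other libraries left unmodelled it recovered 0% and 76%, with 0 false calls, and with that difference as a term 68% and 100%, with 4% false calls. The simulated difference was averaged over the groups and identical in both, so the term matched it by construction. In the data it correlated between the groups at a Spearman rho of 0.848 across genes. The 4% therefore cannot give the rate of false calls with that term in the data.

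Lists of genes were fixed before the data were examined: 27 in all, covering phototransduction, chromophore and carotenoid handling, eye development, eye pigment, the circadian clock, fatty acid synthesis, triacylglycerol storage, lipolysis and fatty acid oxidation, oxidative phosphorylation, glycolysis, antimicrobial peptides, stress response, detoxification, apoptosis, synaptic transmission, glia, fat body, ovary, testis, sex determination, gut, muscle, hemocytes, cuticle, chemosensation, ribosomal proteins and small RNA pathways. The 26 lists with at least 5 tested members were compared with all other tested genes by limma's pre-ranked camera test, with a preset correlation of 0.01, two-sided. It ran on the z value implied by each of the authors' p-values and the sign of the fold change, with Benjamini-Hochberg adjustment over the lists. An estimated correlation could be had only from the recovered libraries, where camera was run, and fry, which tests a list against no change and not against other genes. In a simulation of 11155 independent z values, 98.5% of shifted and 3% of unshifted lists of 20 genes had an unadjusted p under 0.05. As it held no correlation between genes, it cannot give the rate of false calls for lists of correlated genes. Changed genes on X and on the autosomes (2L, 2R, 3L and 3R), and within 500 kb of mir-210 and on the rest of X, were compared by Fisher's exact test, two-sided.

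Named genes followed a rule fixed at the same time: the 12 changed genes with the largest fold change in each direction, with an average of at least 2 on the scale of log2 CPM and no overlap between the libraries of the groups; up to 4 members of each list with the smallest p; and the genes next to mir-210. The average was taken over the log2 CPM of the 2 group means, which leaves out genes near 0 in either group, and overlap was not required for genes with a mean over 10000. Genes outside this rule are said to be chosen after their values were seen.

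Alternatives were a threshold of 2-fold, limma on the recovered libraries, a pseudocount of 0.1, no filter on low values, equal library totals, each library left out in turn (also for the group means of named genes), the deepest library of each group as a term or left out, and removal of the trend with gene length by lowess. Gene IDs were matched to Ensembl BDGP6 release 115: 13318 were found, all on the same chromosome and strand, and 99.9% with the same start or end. The position of mir-210 comes from that annotation. Genes with miR-210 seed sites in their 3' UTRs were to be tested, but genome sequence was not used here and this test was not run. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and numba 0.67.0 were used.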

Results

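RNA sequencing compared heads of adult flies described as miR-210 mutant with heads of w1118 control flies, 3 samples per group. The values were the authors' group means of normalized counts with their own fold changes and p-values, and libraries recovered from those means for 97.3% of genes. Reads in recovered genes numbered 9194231, 7406261 and 6257409 in the mutant libraries and 16462836, 9535336 and 8915003 in the control libraries. Nothing in the labels says that the samples came from separate groups of flies, so p-values measure only the spread between these samples, which may be technical. The deepest library of each group differed from the other 4 libraries, and medians within these 2 sets are given for each called list with at least 5 members recovered.

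The comparison asks which transcripts of the head differ between mutants of miR-210, a microRNA encoded on X, and the control strain. In mutant heads, transcripts of the light-sensing machinery of photoreceptors were lower, and transcripts of fatty acid metabolism, fat body proteins and several detoxification enzymes were higher. None of these groups was called with an estimated correlation (adjusted p from 0.161 to 0.585). That test covered only recovered members and left out abundant changed genes of several groups. Rh5, a rhodopsin of the compound eye, fell most clearly, with an authors' mean of 215 in the mutant and 7027 in the control, 32.7-fold lower. Its libraries ranged from 190 to 236 in the mutant and from 5948 to 7643 in the control. Spn42De, a serine protease inhibitor, showed the opposite pattern, with an authors' mean of 1751 against 10.7, and libraries from 1590 to 2067 against 6.39 to 14.9.

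Of 11155 tested genes, 497 changed in the authors' deposited table at an adjusted p under 0.05, 286 higher and 211 lower in the mutant. At an unadjusted p under 0.05 the authors' deposited table has 1357 genes. Of the 439 changed genes recovered in all libraries, 436 had no overlap between the 3 mutant and 3 control libraries. Among all 10783 tested genes recovered, 18.3% had no overlap, where chance gives 10%. limma on the recovered libraries called 115 genes, 50 higher and 65 lower, and all 115 were among the authors' calls in the same direction. With the deepest library of each group as a term limma called 1855 genes, 818 higher and 1037 lower, among them 431 of those 439. With the deepest library of each group left out it called 865, 377 of them shared. The share of higher genes was 57.5% in the authors' calls, 43.5% in the limma calls and 42.2% when libraries were scaled to equal totals. These shares cover unlike sets of genes, since limma tested recovered genes only, which hold 439 of the authors' 497 calls.

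**Figure D1:**
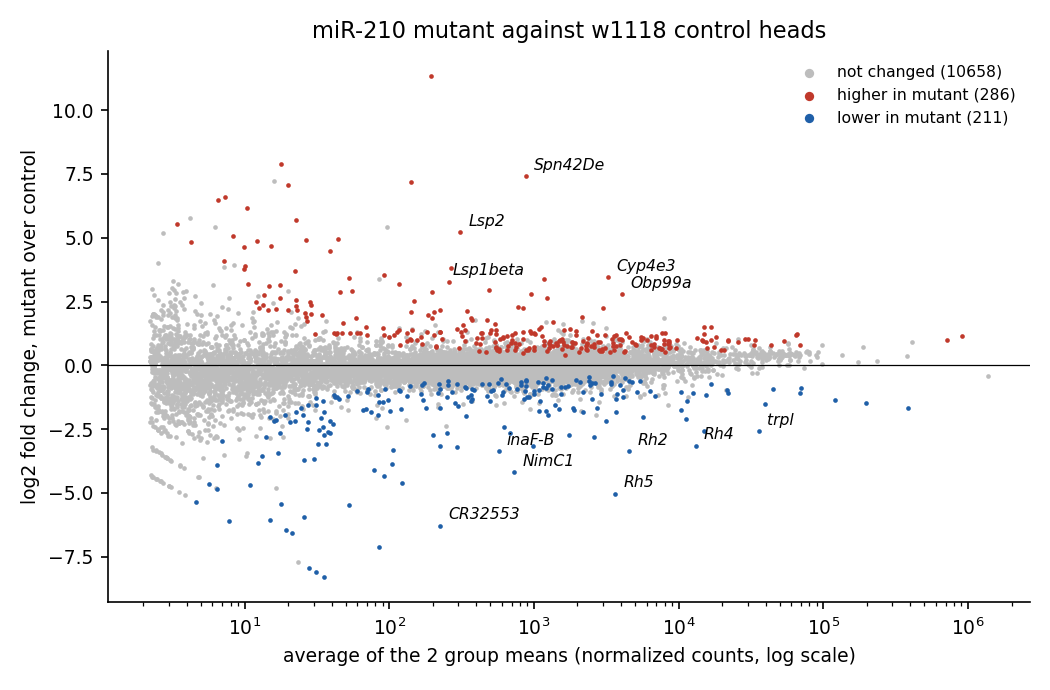
Each point is 1 of the 11155 tested genes, with the average of both group means of normalized counts on a log axis and the authors' log2 fold change, mutant over control, on the vertical axis. Red points are the 286 genes higher and blue points the 211 genes lower in the mutant at an adjusted p under 0.05, with Spn42De at 7.40 and Rh5 at -5.03.

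At the mutated locus, mir-210 lies on X from 18128219 to 18128318 (plus strand, BDGP6) and has no row in the table used. The nearest row on its left, the noncoding RNA CR32553 (X from 18124575 to 18127027, minus strand), was almost absent from the mutant, with an authors' mean of 5.80 against 444. In the authors' deposited table its log2 fold change was -6.28 (adjusted p = 1.2e-27), and its libraries ranged from 2.06 to 10.9 in the mutant (mean 3.26 without the middle library) and from 324 to 563 in the control. The nearest row on its right, the protein-coding gene CG43133 (X from 18129585 to 18130178, minus strand), had an authors' mean of 16.4 in the mutant and 0.387 in the control. Its log2 fold change in the authors' deposited table was 5.06 (adjusted p = 0.00497), at a low level, with 8.93 to 25.7 in the mutant libraries and 1.16 in the deepest control library, the other control libraries being at 0. The muscle gene wupA (-0.50, adjusted p = 0.185) and the ubiquitin ligase gene ari-1 (-0.37, adjusted p = 0.908) were not changed in the authors' deposited table, and neither were Taf8 (0.18), CG7135 (0.26) and CR45606 (1.95, adjusted p = 0.576), the other tested genes within 25 kb. CG43133 lies beside ari-1 on the same strand, and reads running past the end of a gene cannot be separated here.

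**Figure D2:**
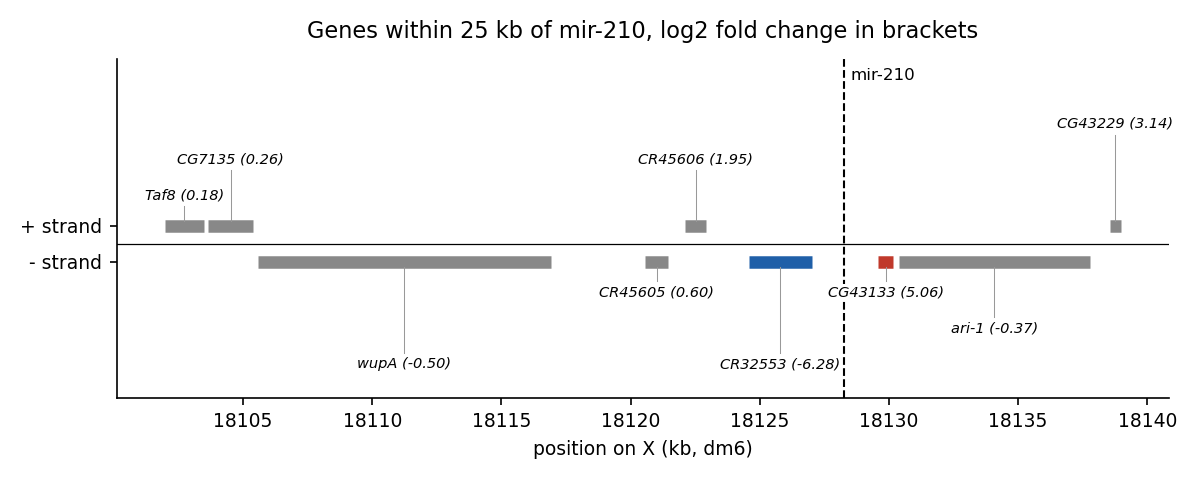
Map of X within 25 kb of mir-210 (dashed line), with genes of the table as bars on their strand, position in kb on build dm6, and the log2 fold change of mutant over control in brackets. CR32553 (blue, -6.28) was lower and CG43133 (red, 5.06) higher, while the grey genes did not pass the test or, for CR45605 and CG43229, were not tested.

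Phototransduction genes were the group that fell most. Of 30 tested members, which include the cascade from rhodopsin to the light-gated channels, 20 fell and 0 rose, and 23 fell when adjusted over the list alone. Their median log2 fold change was -1.13 (camera, adjusted p = 9.9e-68; adjusted p = 0.161 with an estimated correlation, over the 14 members recovered). In the authors' deposited table Rh5 fell by 5.03 on the log2 scale (adjusted p = 4.4e-119), Rh2, the rhodopsin of the ocelli, fell by 3.36 (1.4e-34), and the ultraviolet-sensitive rhodopsins Rh4 and Rh3 fell by 3.14 (1.0e-17) and 2.56 (2.4e-31). The channel subunit gene trpl fell by 2.59 in the authors' deposited table, from an authors' mean of 61427 to 10233 (adjusted p = 4.3e-38). inaF-B, needed for function of the other channel, fell by 3.36 in the authors' deposited table (adjusted p = 8.2e-09), with an authors' mean of 100.5 in the mutant that became 64.9 without the deepest library. Members chosen after their values were seen show the range: ninaE, the main rhodopsin, had a log2 fold change of -1.67 (adjusted p = 0.00222), Rh6 of -1.08 (adjusted p = 0.0712) and the corneal protein gene retinin of 0.03 (adjusted p = 0.992) in the authors' deposited table. The gene of the other channel, trp, also chosen after its values were seen, had -1.08 (adjusted p = 1.4e-08) in the authors' deposited table. Within the deepest library of each group the median of the recovered members was -1.07, and in the other 4 libraries -0.79.

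Genes of eye development and photoreceptor identity were lower as a group, with a median of -0.38 over 18 tested members (camera, adjusted p = 0.00701; adjusted p = 0.701 with an estimated correlation). Here 2 fell and 0 rose, and 3 fell adjusted over the list alone. They were chp, which encodes a photoreceptor surface protein (-1.09, adjusted p = 5.3e-07 in the authors' deposited table), and Pph13, a homeobox regulator of rhodopsin genes (-0.79, adjusted p = 0.0455). The median was -0.24 within the deepest libraries and -0.51 within the other 4, and it shrank to -0.17 after removal of the trend with gene length (camera, adjusted p = 0.0232). The call was lost without the deepest control library (adjusted p = 0.14) and without the shallowest mutant library (adjusted p = 0.322), and fry gave 0.434. Of the lists beside these, chromophore and carotenoid handling (8 tested, adjusted p = 0.946) and eye pigment genes (17 tested, adjusted p = 0.486) had 0 changed members, and 0 adjusted over the list alone.

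Transcripts of fatty acid metabolism were shifted upward in mutant heads, though most list members did not pass. Those of the fat body, the tissue that stores fat, shifted with them (list median 0.78; adjusted p = 0.321 with an estimated correlation). Of 25 tested genes of fatty acid synthesis and its regulator SREBP, 7 rose and 0 fell, and 11 rose adjusted over the list alone. The median was 0.59 (camera, adjusted p = 2.5e-09; adjusted p = 0.161 with an estimated correlation). In the authors' deposited table the malic enzyme gene Men rose by 1.10 on the log2 scale (adjusted p = 9.5e-13), ATPCL, the ATP citrate lyase, by 0.99 (2.8e-08), the isocitrate dehydrogenase gene Idh by 0.98 (0.00028) and Desat1, the fatty acid desaturase, by 0.78 (0.000304). The other 3, chosen after their values were seen, were FASN1 (1.23), ACC (0.98) and AcCoAS (0.93), which encode the steps from acetate to fatty acid. Over the recovered members the median was 0.25 within the deepest libraries and 0.16 within the other 4. None of the 7 changed genes is among the 17 recovered members, as each was too abundant in the mutant to be searched. These medians and the test with an estimated correlation leave out the changed genes, so they cannot show whether the full list weakened.

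Genes of lipolysis and fatty acid oxidation rose too: 4 of 19 tested rose and 0 fell, 11 rose adjusted over the list alone, and the median was 0.60 (camera, adjusted p = 8.9e-07; adjusted p = 0.161 with an estimated correlation). They were bgm, an acyl-CoA synthetase gene (1.27, adjusted p = 3.4e-07 in the authors' deposited table), whd, the carnitine palmitoyltransferase gene (1.08, 4.6e-05), Acox57D-d (0.86, 0.00308) and Mtpalpha (0.88, 0.0195), which act in oxidation of fatty acids. Of 18 tested genes of triacylglycerol synthesis and lipid droplets, 2 rose, Jabba (0.82) and Mtp (0.84), and 0 fell. Adjusted over the list alone 7 rose and 1 fell. Their median was 0.46 (camera, adjusted p = 0.000136; adjusted p = 0.222 with an estimated correlation). Over the recovered members, medians in the deepest and the other libraries were 0.58 and 0.31 for the oxidation list and 0.49 and 0.28 for the storage list. Of the changed genes, the recovered members hold whd, Acox57D-d and Mtp. They leave out bgm, Mtpalpha and Jabba, too abundant in the mutant to be searched, as does the test with an estimated correlation. With the deepest library of each group left out, the storage list was no longer called (adjusted p = 0.0601).

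Fat body transcripts were higher. The fat body is the fly's liver-like tissue, which also lines the head. Of 23 tested genes 8 rose and 1 fell, 12 rose and 1 fell adjusted over the list alone, and the median was 0.78 (camera, adjusted p = 5.1e-07; adjusted p = 0.321 with an estimated correlation). The storage protein genes Lsp2 and Lsp1beta rose from authors' means of 16.0 to 600 and of 205 to 2139, with log2 fold changes of 5.23 (adjusted p = 3.1e-11) and 3.38 (2.4e-05) in the authors' deposited table. Their mutant libraries were spread widely, from 123 to 1068 and from 688 to 4273, and without the shallowest mutant library the means were 366 and 1072. Obp99a, an odorant-binding protein gene, rose by 2.78 and the trehalose synthesis gene Tps1 by 0.78 (adjusted p = 0.000197 and 8.2e-07 in the authors' deposited table). Of the 23 members in the table, 10 also belong to another list. Over the 16 recovered members the medians were 0.47 within the deepest libraries and 0.27 within the other 4. The call ended with the deepest libraries left out (camera, adjusted p = 0.109). It also ended without the deepest control library (0.0859), the deepest mutant library (0.0944) or the shallowest mutant library (0.135), and fry gave 0.202.

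**Figure D3:**
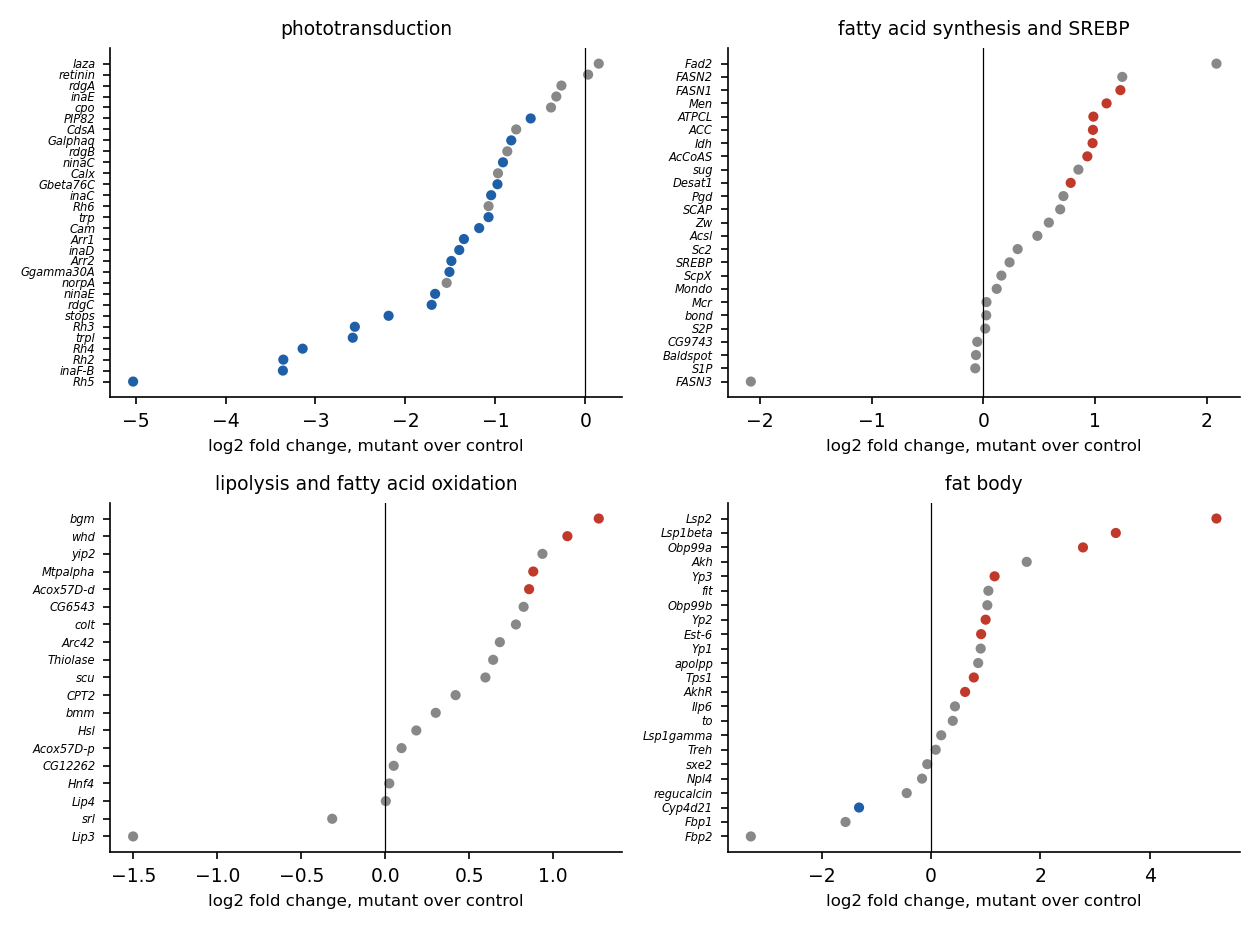
Log2 fold change of mutant over control in the authors' deposited table for each tested member of 4 gene lists, sorted within each panel; red members rose, blue members fell and grey members did not pass the test. Of 30 phototransduction genes 20 fell, while 7 of 25 fatty acid synthesis, 4 of 19 fatty acid oxidation and 8 of 23 fat body genes rose.

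Detoxification genes changed in both directions: of 44 tested, 10 rose and 4 fell, and adjusted over the list alone 11 rose and 4 fell. Their median was 0.21 (camera, adjusted p = 0.000397; adjusted p = 0.585 with an estimated correlation, and 0.0601 with the deepest libraries left out). The cytochrome P450 genes Cyp4e3 (3.47, adjusted p = 3.3e-19), Cyp6a2 (2.24, 6.5e-34) and Cyp6a22 (1.05, 9.1e-08) rose and Cyp4p1 (-3.16, 2.2e-15) fell in the authors' deposited table. Median log2 fold changes were 0.45 within the deepest libraries and 0.11 within the other 4. The call was lost without the deepest control library (camera, adjusted p = 0.0859) and without the deepest mutant library (0.0783), and fry gave 0.215.

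Synaptic transmission genes were lower as a group, with a median of -0.65 over 27 tested members (camera, adjusted p = 0.00038; adjusted p = 0.701 with an estimated correlation). Only 2 members fell, also adjusted over the list alone, and 0 rose: Hdc, the histamine synthesis enzyme of photoreceptors (-1.41, adjusted p = 2.5e-08 in the authors' deposited table), and HisCl1, a histamine-gated channel (-0.85, 0.000202). These genes are long, with a median length of 5778 bases, and they stood 1.94 higher on the log2 scale in the deepest library of each group than in the others. The median fold change was -0.58 within the deepest libraries and -0.76 within the other 4, and after removal of the trend with gene length it was -0.41 (camera, adjusted p = 0.00383). The call was lost without the deepest control library (adjusted p = 0.217) and without the shallowest mutant library (adjusted p = 0.135), and fry gave 0.456.

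**Figure D4:**
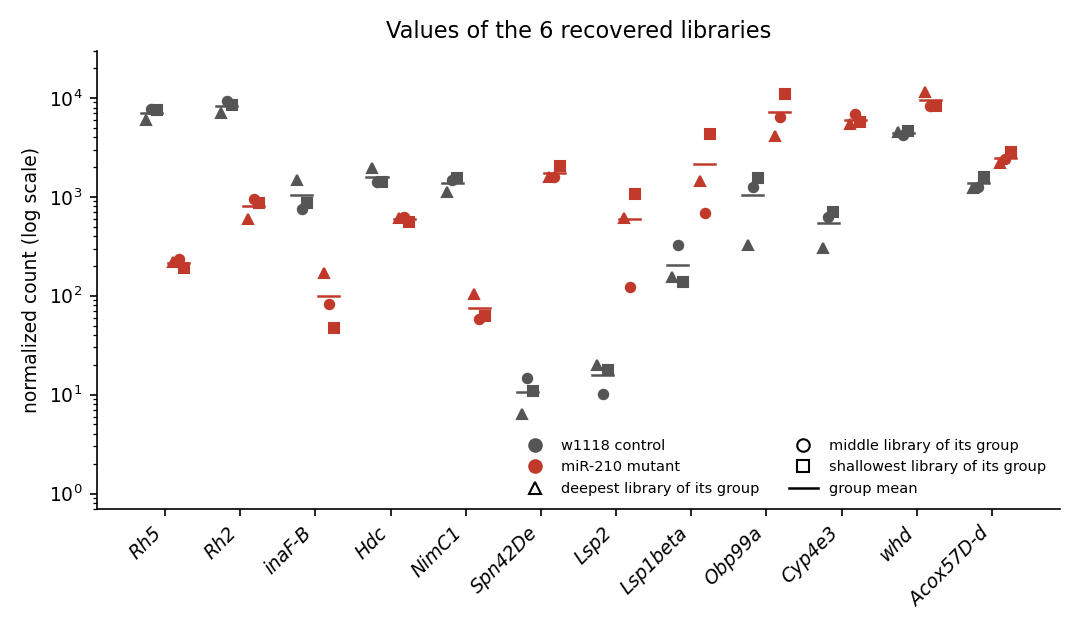
Normalized counts on a log axis in the 6 recovered libraries for 12 genes, control in grey and mutant in red, with triangles, circles and squares for the deepest, middle and shallowest library of each group and bars for the group means. The groups do not overlap for any gene shown, which the rule for named genes required of those with the largest changes. Rh5 lies between 190 and 236 in the mutant and between 5948 and 7643 in the control.

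Ribosomal protein genes had a median of 0.45 with 0 of 33 changed (camera, adjusted p = 0.000136), and glycolysis genes a median of 0.38 with 0 of 14 changed (adjusted p = 0.0093). Neither had any member changed adjusted over the list alone, and neither could be tested in the recovered libraries. Muscle genes had a median of -0.28, and 1 of 22 fell, also adjusted over the list alone, the troponin gene TpnC41C (-1.01 in the authors' deposited table; camera, adjusted p = 0.00845; adjusted p = 0.222 with an estimated correlation). The muscle median shrank to -0.15 after removal of the trend with gene length (camera, adjusted p = 0.0117), and was -0.18 within the deepest libraries and -0.29 within the other 4. Antimicrobial peptide genes had a median of -0.63, with 1 of 30 higher (IM23, 1.19) and 3 lower (edin, -4.12, IM2, -0.83, and CR44404, -2.74) in the authors' deposited table, the same numbers as adjusted over the list alone (camera, adjusted p = 0.0167; adjusted p = 0.863 with an estimated correlation). The antimicrobial median was -0.56 within the deepest libraries and -0.44 within the other 4. This list stood 1.75 lower on the log2 scale in the deepest library of each group than in the others, and the libraries of edin overlapped between groups. Without the middle control library the control means fell from 148 to 71.2 for edin and from 61.3 to 25.4 for CR44404. Mutant means fell from 8.56 to 4.98 for edin without the middle mutant library, and from 9.34 to 5.08 for CR44404 without the shallowest. Its direction turned without the deepest mutant library (adjusted p = 0.864) or without the middle control library (adjusted p = 0.84).

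The other lists were not called. Circadian clock genes (16 tested, adjusted p = 0.439), oxidative phosphorylation (28 tested, 0.486), stress response (22 tested, 0.892), apoptosis (21 tested, 0.509) and small RNA pathways (15 tested, 0.486) had 0 changed members, and 0 adjusted over the list alone. Some clock genes were spread widely within groups, such as vri, from 514 to 3882 in the mutant libraries and from 1028 to 5407 in the control libraries. Without the deepest mutant library oxidative phosphorylation was called higher (limma and camera, adjusted p = 0.0475), and without the middle control library stress response was (0.0203). Glia (18 tested, adjusted p = 0.486) had alrm lower (-0.79), hemocytes (15 tested, 0.439) had the phagocytosis receptor gene NimC1 lower (-4.20), gut (14 tested, 0.486) had Amy-d higher (1.76) and ovary (7 tested, 0.946) had Cp19 higher (3.16) in the authors' deposited table. Without the shallowest mutant library the mutant mean of Amy-d was 354 instead of 580.4, and without the shallowest control library the control mean of Cp19 was 1.51 instead of 3.66. Adjusted over the list alone the counts were the same, except that 1 hemocyte gene was also higher. Cuticle (20 tested, adjusted p = 0.486) had Cpr49Ab (2.19) and Cpr47Ea (1.30) higher, and chemosensory genes (31 tested, 0.593) had Obp99a (2.78) and lush (0.81) higher and Gr64f (-1.19) lower in the authors' deposited table, with the same counts adjusted over the list alone. Among sex-biased genes (14 tested, 0.509) the yolk protein genes Yp2 (1.00) and Yp3 (1.16) were higher and Cyp4d21 (-1.32) was lower in the authors' deposited table, while 4 were higher and 1 lower adjusted over the list alone. The sample labels used give genotype and replicate only, so whether the groups held the same share of females was not tested. Of the 15 sex-biased genes in the table, 7 also belong to another list, and the same limit holds there. Testis genes had 4 tested members, too few for the test, with 0 changed and 0 adjusted over the list alone.

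The rule for named genes leaves out genes near 0 in either group, among which some fold changes are larger. Outside the lists, the largest rise under this rule was in Spn42De (7.40), described above. It was followed by CR31044 (3.82), CG14257 (3.25), the insulin-responsive glycosidase gene tobi (2.95), CG14329 (2.87), CG9150 (2.80), CG3397 (2.63) and the eclosion hormone gene Eh (2.52) in the authors' deposited table. The control mean of CG14257 fell from 49.0 to 27.7 without the deepest control library, and the mutant mean of tobi from 864 to 539 without the shallowest mutant library. The largest falls under it were in Cyp304a1 (-3.18), the myosin gene Myo28B1 (-3.18), gol (-2.80), the noncoding RNA Uhg5 (-2.75), the phosphoesterase gene Mppe (-2.71) and the inositol phosphate kinase gene Ipk1 (-2.67) in the authors' deposited table.

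Changed genes were fewer on X, the chromosome that carries mir-210. On X 40 of 1818 tested genes changed (2.20%), and on the autosomes 449 of 9185 (4.89%), an odds ratio of 0.438 (Fisher's exact test, p = 4.9e-08). Within 500 kb of mir-210, 5 of 87 genes changed, against 35 of 1731 on the rest of X (odds ratio 2.95, Fisher's exact test, p = 0.0392). Those 5 include CR32553 and CG43133, which lie beside mir-210, and the comparison was not run without them. Within 1000 kb 7 of 164 changed, against 33 of 1654 (odds ratio 2.19, Fisher's exact test, p = 0.0843). Genes are not independent replicates. With limma calls on the recovered libraries the X odds ratio was 0.79 (Fisher's exact test, p = 0.443), 0.905 (p = 0.166) with the deepest library as a term and 0.808 (p = 0.0414) with the deepest libraries left out. The 500 kb comparison gave 3.02 (p = 0.166), 2.02 (p = 0.00934) and 2.14 (p = 0.0422) by Fisher's exact test in the same fits.

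**Figure D5:**
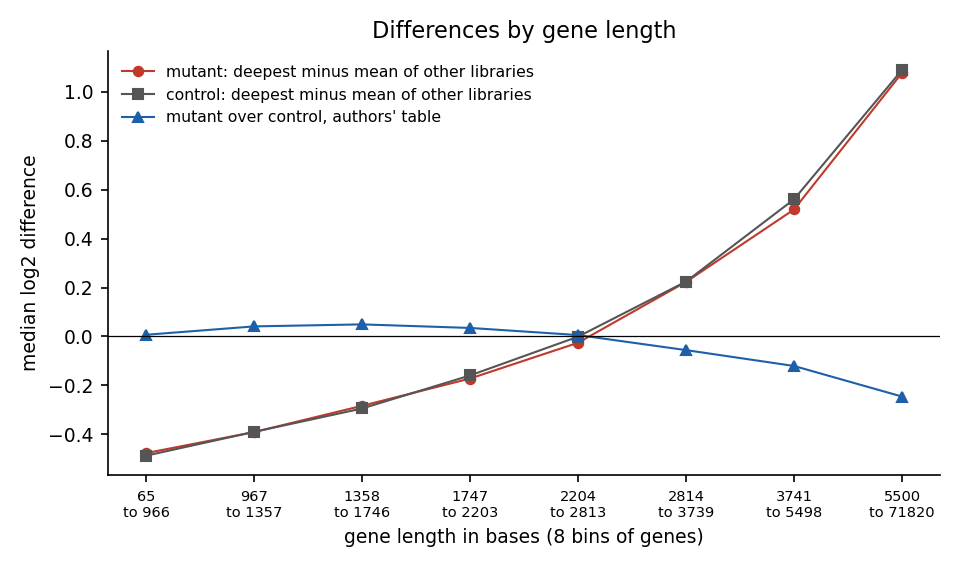
Median log2 differences in 8 bins of gene length, for 8917 genes with a mean of at least 20 in the recovered libraries: deepest library minus the others within the mutant (red) and within the control (grey), and the authors' log2 fold change of mutant over control (blue). The differences within each group rise from -0.48 and -0.49 in the shortest genes to 1.08 and 1.09 in the longest, while the fold change falls from 0.01 to -0.25.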

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

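All tests in this part were chosen after the results were seen, except the comparison of X with the autosomes within expression deciles and for 8-fold changes, which were written before their values were seen.

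In the authors' deposited table, means but no p-value are given for 23 genes, which entered no comparison; 16 of them have a mutant mean above the control mean. In the recovered libraries all 16 have their highest value in the shallowest mutant library and the other 7 in the deepest control library. For 22 of the 23 genes over 50% of the summed values lay in that 1 library, with a median of 83%. The sodium channel gene para, with means of 733 and 1299, was the exception at 49.1%. Several of the 16 were also high in the middle control library, such as CG34220 (1904) and CG34324 (1079), while others, such as yip7 (0), were not. The shallowest mutant library also raised the mutant means of Lsp2, Lsp1beta, Amy-d and tobi, as given above. The cause was not tested.

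The deepest library of each group lay at 1 end of the first principal component, which held 58.4% of the variance. Loadings were 0.36, -0.25 and -0.62 in the mutant and 0.64, -0.12 and -0.01 in the control, from deepest to shallowest. They form a gradient and not 2 clear sets, so a term for the deepest libraries describes it only in part. Size factors were at most 0.973 in the mutant and at least 1.00 in the control, so depth and genotype cannot be told apart. Between the deepest libraries and the other 4, limma called 4721 genes with genotype as a term. The difference rose with gene length in both groups (Spearman rho of 0.677 in the mutant and 0.703 in the control, across 8917 genes, which are not independent replicates), consistent with fewer reads from long transcripts in the other 4 libraries. Among the gene lists, synaptic genes were higher (adjusted p = 3.6e-11) and antimicrobial (3.6e-10) and oxidative phosphorylation genes (4.7e-05) lower in the deepest libraries by limma's camera, and the design names no biological difference between these libraries. After removal of the length trend 5 of 7 clock genes (Clk higher; per, tim, vri and Pdp1 lower) lay on the side of 1 phase in both groups, while cry and cwo did not. The differences in mutant and control were 1.25 and 1.99 for Clk and -3.14 and -2.71 for vri. They were -1.44 and -2.59 for per and -1.48 and -1.53 for tim. On the other side they were smaller, at -0.12 and -0.38 for cry and 0.26 and 0.18 for cwo. Pdp1 counts only narrowly, at -0.02 in the mutant against 1.40 before that removal, and without it the count would be 4. Before that removal per (-0.91 and -2.02), tim (-0.63 and -0.65) and vri (-2.56 and -2.10) were already lower in mutant and control. The length trend places genes of their length higher, so it alone does not account for them. Clk, Pdp1 and cwo were higher and cry lower before it. The count of clock genes leaves the sizes aside, and by it another time of collection cannot be told apart from a technical difference.

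The phototransduction list was lower in the mutant. An equal loss of photoreceptors for every gene of the list is argued against as the whole cause by the rhodopsins, whose fold changes differed (Cochran's Q of 130 against a chi-square distribution, p = 2.0e-26, log2 fold changes from -5.03 to -1.08). That test is approximate, with 3 libraries per group, and rests on standard errors implied by the authors' p-values. Fewer reads from long transcripts are argued against too, since after removal of the length trend the median was -1.08 and the list remained called at the preset correlation (adjusted p = 1.5e-66; 0.161 with an estimated correlation, before that removal). The channel genes trpl and trp also changed unequally, at -2.59 (implied standard error 0.19) and -1.08 (0.16). Both were picked after their values were seen, and expression by photoreceptor type was not measured. They therefore cannot decide on an unequal loss of photoreceptor types. The genotype difference itself, an unequal loss of photoreceptor types and other differences between the 2 strains may each account for the pattern and stay open, as untested hypotheses.

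Fewer genes changed on X than on the autosomes. Lower expression of X genes is argued against by the comparison within 10 deciles of mean expression, with an odds ratio of 0.448 and an upper 95% bound of 0.623. Autosomal differences between the 2 strains may contribute: for changes of 8-fold or more the odds ratio was 0.504, but its 95% interval of 0.217 to 1.17 spans 1, with 6 such genes on X and 60 on the autosomes. Strain and mutation cannot be told apart in this design. The pattern also depends on the test, since limma calls on the recovered libraries gave 0.79 without passing, and 0.808, which passed, with the deepest libraries left out.

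The limma count of 115 genes was compared with other divisions of the 6 recovered libraries into 3 and 3. Of 10 splits 1, the real one, gave as many, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.1. At an unadjusted p under 0.05 the real split called 1296 genes, and a split with the deepest libraries on the same side called 2128, which points to the structure described above.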

How the results depend on the processing

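The limma fit to the recovered libraries, the deepest library as a term or left out, and the length checks were chosen after the table was seen. No paired analysis was possible because the columns are group means and carry no replicate numbers. TMM and other size factors in a count model, the count-based tests, a replicate block and the seed-site comparison were not run. The authors' 497 calls fell to 316 with a 2-fold threshold as well. limma on the recovered libraries, where 372 abundant genes are missing, called 115 genes, 90 with a pseudocount of 0.1, 107 without a filter, 109 with equal totals, 1855 with the deepest library of each group as a term and 865 with that library left out; leaving out each library in turn gave 23 to 75. All 439 authors' calls tested there kept their sign in each of these fits. This was nearly fixed in advance, since 436 of the 439 had no overlap between the libraries of the groups. Of the named genes recovered, 23 passed in the same direction with limma and 23 did not pass, against 41 and 5 with the deepest library as a term. In the simulations above the library difference alone lowered the calls; other causes were not tested.

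Of 12 lists called, all 12 remained after removal of the length trend. Only 10 of them could be run on the recovered libraries, over recovered members alone and without ribosomal proteins and glycolysis. Of these, 9 remained with limma, 10 with the deepest library as a term, 7 with the deepest libraries left out and 0 with an estimated correlation, with or without that term. fry asks another question, whether a list changed at all rather than more than other genes, and passed 4 of the 10. The antimicrobial list was lost with limma (adjusted p = 0.116), and triacylglycerol, detoxification (both 0.0601) and fat body (0.109) with the deepest libraries left out. Not passing by fry were eye development (0.434), antimicrobial (0.744), detoxification (0.215), synaptic (0.456), fat body (0.202) and muscle (0.0715). With each library left out in turn 6 to 10 lists were called, of which 6 to 9 were among the 12. Lost were eye development (0.14), detoxification (0.0859), synaptic (0.217) and fat body (0.0859) without the deepest control library, detoxification (0.0783) and fat body (0.0944) without the deepest mutant, eye development (0.322), synaptic (0.135) and fat body (0.135) without the shallowest mutant, muscle (0.0693) without the middle mutant and antimicrobial (0.214) without the shallowest control library. Called beyond the 12 were oxidative phosphorylation, higher without the deepest mutant library (adjusted p = 0.0475; 0.0475 to 0.737 over the libraries left out), and the stress list. The antimicrobial list turned upward without the deepest mutant library (adjusted p = 0.864) and without the middle control library (0.84), and the stress list upward without the middle control library (0.0203). With each library left out, adjusted p ranged from 1.9e-05 to 0.864 for the antimicrobial list and from 0.0203 to 0.818 for the stress list; the cause was not tested.

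The X odds ratio was 0.438 with the authors' calls, kept its call at 0.448 within expression deciles and 0.808 with the deepest libraries left out (p = 0.0414), and lost its call at 0.79 with limma, 0.905 with the deepest library as a term, 0.886 with a pseudocount of 0.1, 0.807 without a filter, 0.842 with equal totals, and 0.242 to 0.98 with each library left out. The 500 kb odds ratio kept its call at 2.02 with the deepest library as a term (p = 0.00934) and 2.14 with those libraries left out (p = 0.0422), and lost its call at 2.19 in the 1000 kb window, 3.02 with limma, 1.62 with a pseudocount of 0.1, 3.21 without a filter and 3.02 with equal totals, and ranged from 2.43 to 19.7 with each library left out; without the shallowest control library it had no value, as the only changed X gene lay within the window (Fisher's exact test, p = 0.0491). Few genes were called with 1 library left out, 23 to 75; in the simulation the library difference gave 76 calls outside the model and 175 as a term. With that term 1855 genes were called here, and why the X odds ratio moved was not tested.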

Other observations

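All observations and tests here were chosen after the values were seen.

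Several serpin genes rose. Of 20 tested genes that the authors' annotation assigns to the serpin family, which inhibit serine proteases, 6 were higher and 14 were not changed (30.0% higher against 2.78% of all 4324 annotated genes; hypergeometric test, p = 1.1e-05, adjusted p = 0.0016 over 141 families in both directions). Neighbouring genes on 2R were among them in the authors' deposited table: Spn42Da (0.75), Spn42Db (4.93), Spn42Dc (1.45) and Spn42De (7.40), with Spn42Da starting at 6875906 and Spn42De ending at 6888262. Close copies can share reads, so their single values are uncertain. Spn47C (1.40) and CG43366 (2.37) lie apart from them. Cytochrome P450 genes were enriched among higher genes, with 13 of 80 (adjusted p = 5.6e-05), and so were aldo-keto reductases, with 4 of 12 (adjusted p = 0.0188), and short-chain dehydrogenases, with 7 of 47 (adjusted p = 0.0188). Another 6 P450 genes were lower (adjusted p = 0.163). Genes are not independent replicates.

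Some genes were listed at 0 in 1 group. CG15534 had an authors' mean of 388 in the mutant, with libraries from 317 to 505, and was listed at 0 in the control. CG7386 had an authors' mean of 61.9 in the control, with libraries from 47.4 to 69.7, and was listed at 0 in the mutant. Of 3 tested Y-linked rows, 2 changed. These are unnamed intervals of the authors' own annotation, which places them in the reverse transcriptase family RVT_2. Whether their reads come from the Y was not tested. The interval from 3503254 to 3505517 had means of 3.76 in the mutant and 47.4 in the control, and the interval from 3451067 to 3456749 had means of 20.6 and 0.332, but 6.74 in the mutant without its deepest library, and its control value came from the shallowest library alone.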
